A study of Mus musculus with 9 samples.

How the data were processed

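RNA was measured in 9 libraries of mouse CD4 T cells. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with an Ion Torrent total RNA kit. Per the submitters' processing notes, bedtools and the mm10 build were used. The aligner, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes are uncertain.

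The authors deposited 1 table with a coverage signal for 23171 gene rows in each library. Tested on the values, each signal equals the summed base coverage plus 1 base, divided by the library total and multiplied by the mean of the 9 totals, 333 megabases. Base counts recovered this way were whole in 100% of values within 1e-06, but reads cannot be recovered from bases. The deposited table also holds the authors' group means, the ratio of means as a fold and an unadjusted p-value. These were recomputed within 1e-12 as a two-sided equal-variance test on the linear values.

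The 1 added base is worth 0.416 to 5.26 deposited units, depending on the library. It was therefore removed, and values were set on a scale of bases per Mb. The design fixed before the data were examined named log2(value + 1) of the values as deposited with 9 separate samples, and the analysis departs from it in this scale and in the naive samples. Naive replicates 1 and 2, described as 1A and 1B, gave a median chi-square ratio of 0.993 at an assumed 100 bases per read, against 6.32 to 17.8 for the other pairs within groups. The ratio was 1.10 at 90 bases per read and 0.823 at 120, and genes with 10000 bases or more varied like reads of 117 to 209 bases. Naive replicates 1 and 2 were averaged. Both choices came from the structure of the table and not from test results, and the design as written was run as an alternative.

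Genes with a mean of at least 1 base per Mb were tested with limma 3.58.1 in R 4.3.3. The model took log2(bases per Mb + 1), all groups in 1 fit, a variance trend and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. In simulated data with a log2 SD of 0.5, 86% of 4-fold and 12% of 2-fold changes were recovered between Hopx high and Hopx low, among 10817 genes. For Hopx high against naive 74% of 4-fold changes were recovered, and for Hopx low against naive 68% among 10773 genes. The SD of 0.5 was a setting and was not estimated from the data. Between Hopx high and Hopx low 100% of simulated 8-fold changes were recovered. In the data Tbkbp1, at a log2 difference of 2.94, did not pass in the fit to all groups (adjusted p = 0.269). The simulated shares may therefore overstate what that fit could find.

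Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Of 736 listed genes 34 were not matched to a row and 11 were matched by an older symbol. Named genes followed a rule fixed before the data were examined. Hopx, Ifng, Tbx21, Foxp3 and Il2 were always named where tested. Next came the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose higher group mean was at least 5, leaving out clone and accession names, small non-coding RNAs and receptor or immunoglobulin segments. Where no gene passed, the 5 with the smallest p were named. From each list described, up to 4 called members with the smallest p could be named, or up to 2 with the highest mean where none passed. The rule was applied to the 6-library fit as well, and not every gene it picks is named in the text. Ifng lay below the filter.

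Same-numbered Hopx low and Hopx high samples deviated together over 6078 genes, with r of 0.47, 0.48 and 0.18, so the numbers pair them, by the rule that each of 3 or more pairs has an r over 0.1. Naive numbers did not meet that rule and were not taken as pairs. Alternatives were the scaling, filter, pseudocount, trend, replicate block, samples in the fit and leaving out each replicate. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.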

Results

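RNA was sequenced from CD4 T cells taken from the lymph nodes and spleen of C57BL6 mice. Per the labels, chimeric antibodies that carry an antigen to dendritic cells were injected 5 days before the first sort, and the sorted T cells were restimulated with antigen-presenting cells for 12 h and sorted again. The 9 libraries fall into 3 groups of 3, called naive, Hopx low and Hopx high. Hopx is a small homeodomain protein that does not bind DNA. The comparisons ask how the RNA of antigen-specific T cells with different levels of Hopx differs after restimulation. The treatment label is shared by all 9 libraries and does not say which animals the naive cells came from. It also does not say that replicates came from separate animals, so p-values measure only the spread between these samples.

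Summed coverage over 23171 gene rows was 63.3, 86.5 and 289 megabases in naive replicates 1, 2 and 3. It ranged from 330 to 442 megabases in Hopx low and from 203 to 800 megabases in Hopx high. Between 9723 and 13123 rows had coverage above 0. Values are given as bases per megabase (Mb) of summed coverage. A read of 100 bases, a length assumed here, is worth 0.125 to 1.58 bases per Mb, and lower values were not resolved. Gas5, a non-coding host gene of small nucleolar RNAs, held 1.16% to 40.0% of the coverage of a library. At the median over genes, naive replicates 1 and 2 differed far less than any other pair within a group, by about the sampling noise if a read covers 100 bases. The most covered rows differed more, with Gas5 at 40.0% of the coverage in naive replicate 1 and 29.1% in naive replicate 2. These 2 libraries were counted as 1 sample, so naive has n = 2. Over 6078 genes naive replicate 3 had r of 0.653 and 0.647 with naive replicates 1 and 2, but 0.871 with Hopx low replicate 3. Naive replicate 1 had 0.847 with Hopx low replicate 1. The naive samples were thus less like each other than like some Hopx libraries, and every comparison with naive rests on them.

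**Figure D1:**
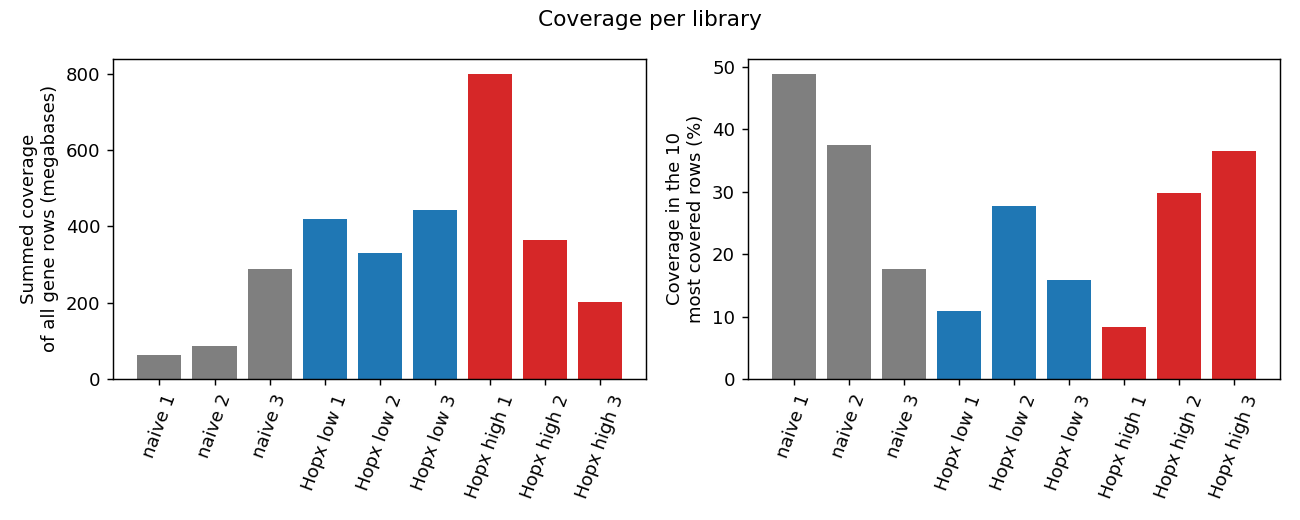
Summed coverage of all gene rows in megabases (left) and percent of coverage in the 10 most covered rows (right), 1 bar per library, coloured by group. Naive replicates 1 and 2 have the lowest totals, 63.3 and 86.5 megabases, and the largest top 10 shares, 48.9% and 37.5%.

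Hopx itself had 8.95, 7.79 and 4.89 bases per Mb in the Hopx high libraries and 3.32, 6.90 and 3.29 in the Hopx low libraries. In naive it was listed at 0, 0 and 1.64. The gene lies on chromosome 5 at 77086988 to 77115121 of GRCm38. The Hopx high library was above the Hopx low library of the same number in 3 of 3 pairs, while the groups overlapped. The log2 difference of 0.60 ± 0.59 (SE) did not pass (adjusted p = 0.992, and 0.975 with a replicate block). Xist, the RNA that coats the inactive X chromosome, had 89.1, 76.1 and 263 bases per Mb in naive and at most 0.400 in any Hopx library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 17.7 to 85.5 in the Hopx libraries and at most 0.300 in naive. The naive and Hopx libraries therefore also differ in sex-linked rows, beside every comparison with naive.

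No gene differed between Hopx high and Hopx low at an adjusted p of 0.05 in the limma fit to all 3 groups. Limma without a variance trend called 0 genes as well. The smallest adjusted p was 0.269, and 487 of 10825 genes had an unadjusted p under 0.05, 224 higher and 263 lower. By the authors' deposited p-values 884 of 23171 rows had an unadjusted p under 0.05, 335 higher and 549 lower, and 1 passed after adjustment here. Both are smaller shares than the 0.05 that chance gives on average. Tbkbp1, Hist1h3c, Pkdcc, S1pr1 and Txnip had the smallest p of all and did not pass (adjusted p = 0.269 for each). The groups did not overlap for 14.5% of genes, 486 higher and 1088 lower, where chance gives 10%. The 6 Hopx libraries fitted on their own gave 53 genes higher and 16 lower in Hopx high among 10846 tested. Log2 differences were the same in both fits, as for Tbx21 (2.85) and S1pr1 (-2.56). The estimated spread differed, since the naive samples also set it in the fit to all groups. The count of 0 therefore depends on the naive samples too and does not show that the Hopx groups are alike. At an unadjusted p under 0.05 the 6-library fit leaned the other way, with 359 higher and 701 lower. Its median log2 difference over all genes was -0.25, and -0.01 after each library was divided by its median gene. These counts, and the 486 and 1088, are to be read against that shift. That fit was an alternative planned before the data were examined, and it was made a result of its own only after the count of 0 was seen. The adjusted p-values of single genes in the next 3 paragraphs come from it, and they leave out the pairing by replicate number. With a replicate block added 75 genes were called, and 57 of the 69 were among them.

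Of the Th1 effector genes 3 of 17 were called higher in Hopx high: Tbx21, Il12rb1 and Il12rb2. In these 6 libraries the list had an adjusted p = 0.428 with an estimated correlation. Tbx21, the transcription factor T-bet, had 72.6 ± 37.7 bases per Mb (SD, n = 3) in Hopx high and 9.35 ± 5.56 in Hopx low (log2 difference 2.85, adjusted p = 0.00136). It lies on chromosome 11 at 97098071 to 97115331. Il12rb1 and Il12rb2, which encode the chains of the interleukin 12 receptor, differed by 1.70 (adjusted p = 0.0215) and 1.90 (adjusted p = 0.0323). Tbkbp1 had the largest rise, 52.2 ± 5.45 against 6.06 ± 1.74 (log2 difference 2.94, adjusted p = 0.000358), followed by Ptpn5 at 2.93, Tbx21, and Pkdcc at 2.79. Il13, a T helper 2 cytokine, had 18.6 ± 6.96 against 2.86 ± 3.37 (adjusted p = 0.00988). Every Hopx high library lay above every Hopx low library for these genes. The naming rule required this of the largest rises, among them Tbkbp1, Ptpn5, Tbx21, Pkdcc and Il13, so it adds no support for them. Foxp3 (5.54 ± 2.45 against 3.88 ± 1.21, adjusted p = 0.801) and Il2 (33.9 ± 19.9 against 38.1 ± 3.66, adjusted p = 0.789) did not pass.

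Histone genes, in the fixed list or not, made up 29 of the 53 higher genes. Of the fixed histone list 15 of 31 were called higher. In these 6 libraries that list had an adjusted p = 0.224 with an estimated correlation. Hist1h3c had 440 ± 232 bases per Mb in Hopx high and 71.5 ± 9.24 in Hopx low (log2 difference 2.45, adjusted p = 0.00163), and Hist1h2ah differed by 2.73. These genes are near-identical copies, and how coverage was shared between them is not given in the sources used here. Of the G1/S genes 1 of 35 was called higher, E2f1 (1.81, adjusted p = 0.0150), and of the G2/M genes 3 of 36, Ube2c (2.46, adjusted p = 0.0103), Kif11 (1.96, adjusted p = 0.0306) and Mki67 (1.79, adjusted p = 0.0397). In these 6 libraries the G1/S list had an adjusted p = 0.286 with an estimated correlation and the G2/M list an adjusted p = 0.224.

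Of the naive and quiescence genes 5 of 28 were called lower in Hopx high, and of the exit and homing genes 2 of 17. These 2, S1pr1 and Klf2, belong to both lists and are among the 5. In these 6 libraries those lists had an adjusted p = 0.326 and an adjusted p = 0.428 with an estimated correlation. S1pr1, the receptor for exit from lymphoid tissue, had 22.2 ± 11.3 bases per Mb against 130 ± 41.9 (log2 difference -2.56, adjusted p = 0.00136). Klf2, the transcription factor that drives S1pr1, differed by -1.90 (adjusted p = 0.0150), Txnip by -1.83 (adjusted p = 0.0150), Igfbp4 by -1.64 (adjusted p = 0.0277) and the pro-apoptotic Bcl2l11 by -1.58 (adjusted p = 0.0460). Oas2, an interferon-induced enzyme, had 10.2 ± 1.30 against 50.4 ± 8.92 (adjusted p = 0.00590). Tsc22d3 (-1.94, adjusted p = 0.0244), Neurl3 (-1.93, adjusted p = 0.0150) and Tubb2b (-1.91, adjusted p = 0.0496) were lower as well. The B cell gene Cd79a had 0.666 ± 0.421 against 6.26 ± 2.33 (adjusted p = 0.0320).

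The count of 53 and 16 became 0 and 0 with no filter on low values, 1 and 0 with the values as deposited, 23 and 5 without a variance trend and 32 and 9 with a pseudocount of 0.1. It was 75 and 11 with scaling by the median gene and 77 and 11 with quantile normalization, so the lower calls depend in part on the scaling. It became 3 and 2 without Hopx low replicate 3, 7 and 2 without Hopx high replicate 3, 16 and 10 without Hopx low replicate 2, and 15 and 22 without Hopx high replicate 1, where more genes were lower than higher; in the fit to all groups, leaving out naive replicate 3 gave 45 and 12.

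**Figure D2:**
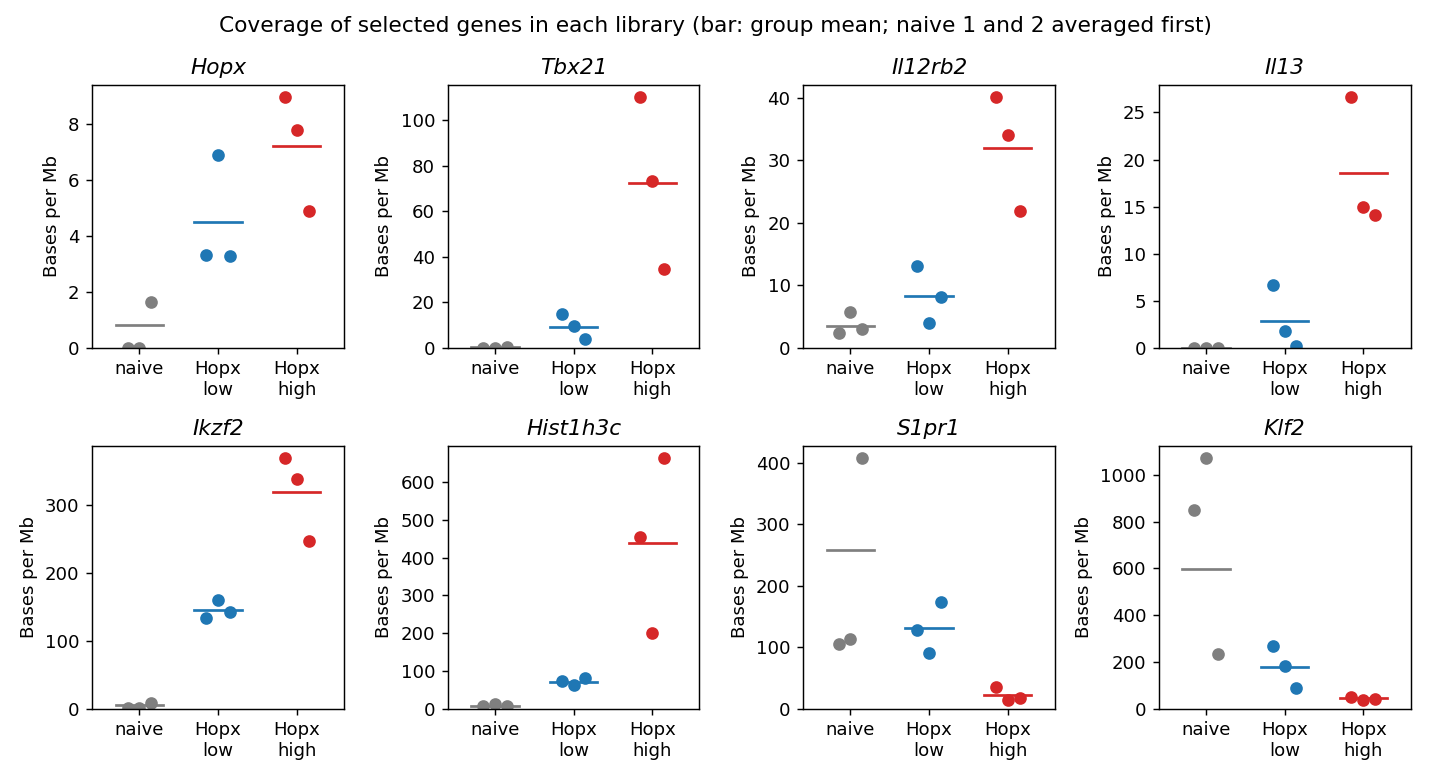
Bases per Mb in each library for 8 genes, 1 point per library, with a bar at the group mean. Tbx21 lies at 34.5 to 110 in Hopx high and 3.72 to 14.8 in Hopx low, while the Hopx groups overlap for Hopx itself.

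Of 36 gene lists fixed before the data were examined, 32 had at least 3 tested members. With camera's preset correlation 15 passed between Hopx high and Hopx low in the fit to all groups, and 0 passed with an estimated correlation or with fry. The median of all genes was -0.25 on the log2 scale and -0.01 after scaling by the median gene, so list medians are to be read against -0.25. Replication-dependent histones had a median log2 difference of 1.70, with 30 of 31 members positive and 23 higher when adjusted over the list alone (adjusted p = 0.0843 with an estimated correlation). G2/M genes had a median of 1.08, with 35 of 36 positive and 2 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). For G1/S genes (median 0.74, 34 of 35 positive), the Treg program (0.46), the Th1 effector program (0.07), the Th2 program (0.83) and the Th17 program (0.77) that adjusted p was 0.319. The Tfh program (0.22), the IFN-gamma response (0.15) and IL-2 and STAT5 targets (0.12) passed with the preset value, and had an adjusted p of 0.797, 0.580 and 0.640 with an estimated correlation. Naive and quiescence genes were lower, with a median of -0.72, 2 of 28 positive and 9 lower when adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). Homing genes (-0.77), the type I IFN response (-0.48), B cell markers (-1.16) and monocyte markers (-0.75) were lower too, with an adjusted p of 0.429, 0.879, 0.319 and 0.319 with an estimated correlation. AP-1, anergy, coinhibitory, early TCR, cytotoxic, Myc, glycolysis, cholesterol, stress response and apoptosis lists did not pass.

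Against naive, 357 genes were higher and 54 lower in Hopx high among 10825 tested. The naive group here is the unlike pair of samples described above (n = 2). Quantile normalization gave 458 and 273, and scaling by the median gene 568 and 177, so the split between directions depends on the scaling. Ikzf2, the transcription factor Helios, had 318 ± 63.2 bases per Mb in Hopx high and 4.89 ± 4.99 (SD, n = 2) in naive (log2 difference 6.06 ± 0.55, SE; adjusted p = 6.86e-06). Tbx21 (5.82, adjusted p = 0.000109), Penk, which encodes proenkephalin (6.14, adjusted p = 0.000232), Hist1h1b (5.80, adjusted p = 5.81e-05), Hist1h3c (5.48, adjusted p = 1.01e-05) and Bmyc (5.28, adjusted p = 0.000201) rose as well. Foxp3, the factor that defines regulatory T cells, differed by 2.35 (adjusted p = 0.0391) and Hopx by 2.30 (adjusted p = 0.0561), which did not pass. Il2 differed by 0.61 (adjusted p = 0.760).

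The Treg program had a median log2 difference of 2.36 and all 17 tested members positive, 9 of them past the threshold, among them Tnfrsf4 (3.33) and Il2rb (2.65). Its adjusted p was 0.232 with an estimated correlation. Coinhibitory receptors had a median of 2.06, with Lag3 (3.21) and Cd200 (3.31) among 4 that passed (adjusted p = 0.409 with an estimated correlation). Of the Th1 list 4 of 17 passed, including Il12rb1 (4.29) and Eomes (2.36), with an adjusted p of 0.444 with an estimated correlation. Histones had a median of 3.03 with 23 of 31 higher, G1/S genes 2.35 with 17 of 35 higher and G2/M genes 2.23 with 16 of 36 higher. Their adjusted p with an estimated correlation was 0.180, 0.232 and 0.180. Chaf1a, a chromatin assembly factor, was listed at 0 in all naive libraries and had 30.8, 36.0 and 29.9 in Hopx high (adjusted p = 0.000109), and Il13 was listed at 0 in naive as well. Among the 54 lower genes were Klf2 (-3.43, adjusted p = 0.00158), S1pr1 (-3.30, adjusted p = 0.00237), Txnip (-3.01, adjusted p = 0.000505), Cd7 (-3.44, adjusted p = 0.00572), Cited4 (-3.12, adjusted p = 0.00494) and Xist, which was listed at 0 in Hopx high (adjusted p = 6.86e-06). Naive and quiescence genes had a median of -0.97, with 7 of 28 lower (adjusted p = 0.396 with an estimated correlation). B cell markers were lower relative to the other genes (median -0.66, 1 of 7 positive), as were ribosomal protein genes (-0.37, 6 of 39 positive), with an adjusted p of 0.536 and 0.553 with an estimated correlation. The B cell call was lost with median scaling (adjusted p = 0.0931). In all 16 lists passed with the preset correlation, 0 with an estimated one and 6 with fry. The counts ran from 137 higher without Hopx high replicate 1 and 13 lower without Hopx high replicate 3 to 2465 and 241 without naive replicate 3. They were 215 and 25 with no filter, 717 and 149 with naive 1 and 2 as separate samples, and 36 and 5 with these groups alone and a replicate block.

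**Figure D3:**
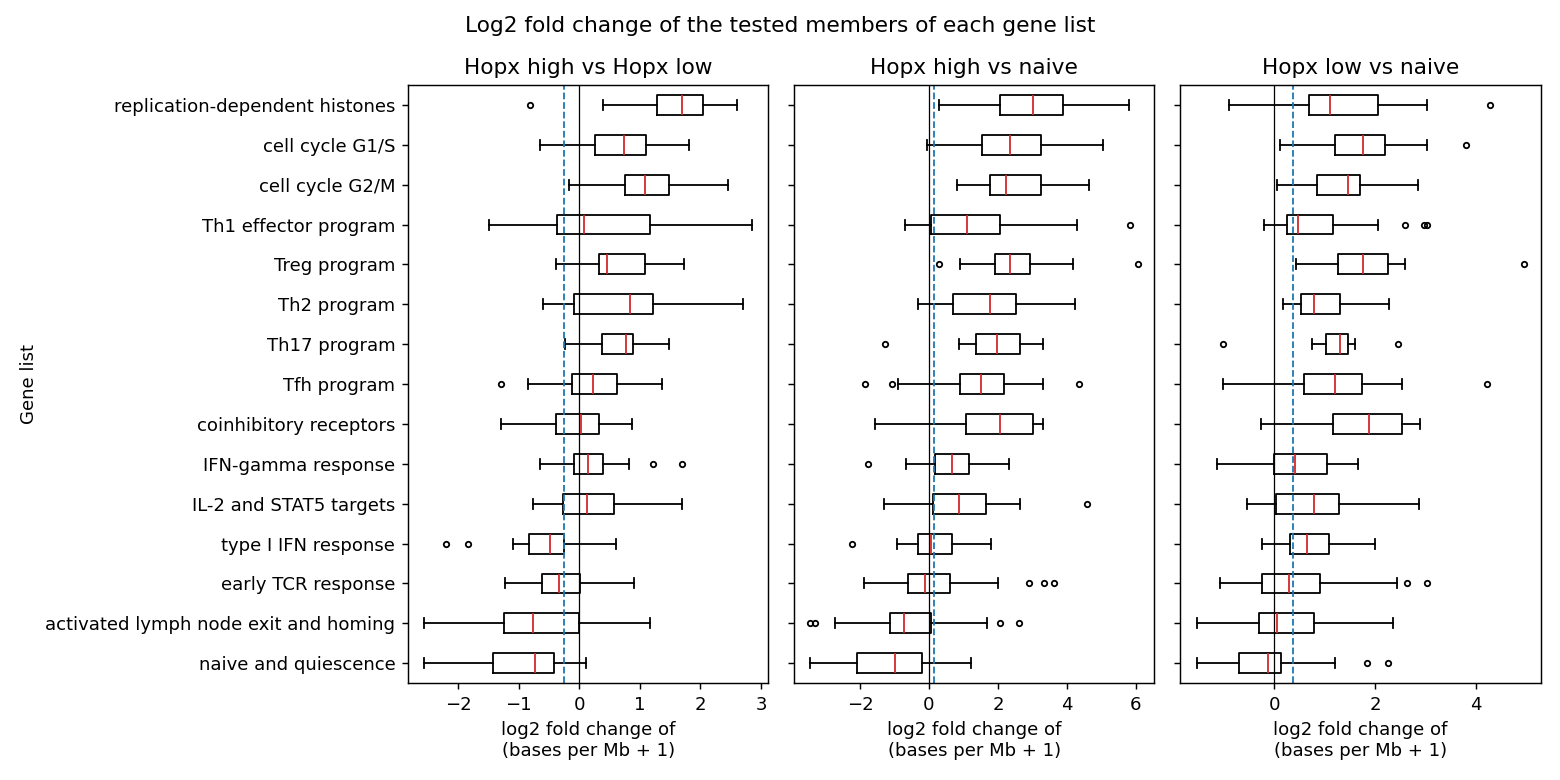
Log2 fold change of the tested members of 15 gene lists in each comparison, as boxes (quartiles, red median, whiskers to 1.5 box lengths, circles beyond). The dashed blue line is the median of all tested genes, -0.25, 0.15 and 0.38 from left to right; the histone list lies above it in each comparison.

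Against naive, 32 genes were higher and 1 lower in Hopx low. Ikzf2 (146 ± 13.6 bases per Mb, n = 3; log2 difference 4.96, adjusted p = 0.000115), Penk (5.05, adjusted p = 0.00478), Cxcr5 (4.23, adjusted p = 0.00539) and Chac1 (3.57, adjusted p = 0.00306) were higher. Lag3 (2.54, adjusted p = 0.0232), Il12rb1 (2.59, adjusted p = 0.0208), Il2rb (2.25, adjusted p = 0.0404), Irf8 (2.64, adjusted p = 0.0131) and Cd83 (3.04, adjusted p = 0.0257) were higher too. The 4 Y-linked genes were among the higher ones, and Xist (adjusted p = 1.14e-05) was the only lower one. Tbx21 (2.97, adjusted p = 0.0856), Hopx (1.70, adjusted p = 0.419), Foxp3 (1.96, adjusted p = 0.254) and Il2 (0.98, adjusted p = 0.726) did not pass. Lists passed in 15 cases with the preset correlation and in 0 with an estimated one. They included the Treg program (median 1.76), coinhibitory receptors (1.89), G1/S genes (1.76), G2/M genes (1.46) and histones (1.11), each with an adjusted p of 0.289 with an estimated correlation. NK cell markers (1.36, 3 of 3 positive) and CD4 T cell identity genes (0.53, 17 of 17 positive) also passed upward, and ribosomal protein genes (-0.05, 16 of 39 positive) and nuclear and non-coding RNAs (-0.04, 6 of 12 positive, with Xist the 1 called) downward relative to the other genes. With an estimated correlation their adjusted p was 0.515, 0.816, 0.639 and 0.289. The NK cell call was lost with quantile normalization (adjusted p = 0.0587) and the CD4 identity call with median scaling (adjusted p = 0.0922). Only 3 of the 15 listed NK cell markers were tested, among them Eomes, also in the Th1 list, and Tyrobp, also in the monocyte list. The counts were 4 higher with these groups alone, 7 with no filter, 82 with the values as deposited and 164 with naive 1 and 2 as separate samples. A replicate block gave 11 higher in the fit to all groups, and 126 higher and 8 lower with these groups alone. They ran from 15 higher without Hopx low replicate 2 to 2690 higher and 83 lower without naive replicate 3.

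The fold changes of both Hopx groups against naive correlated across 10825 genes, which are not independent replicates, with r = 0.848. Unchanged groups simulated with shared naive samples gave 0.601. The covariance was 0.590 against a simulated 0.243, a difference of 0.347. The simulation gave naive and Hopx samples the same spread per gene and did not pair the Hopx samples. In genes of 3000 to 10000 bases, naive replicate 3 differed from 1 and 2 with a robust log2 SD of 0.764 and 0.957. Hopx pairs within a group had 0.470 to 0.751. A wider naive spread or paired Hopx samples would raise the simulated values, so these may be too low. All 32 genes higher in Hopx low were higher in Hopx high, among them the 4 Y-linked genes, so the sex-linked difference common to both comparisons adds to the overlap. In 100 simulations of unchanged groups with shared naive samples, at that same spread, equally long lists of top genes shared 16.9 on average and 10 to 23 in all. Independent lists would share 1.06. Xist was lower in both, where the simulated lists shared 0.40 and independent ones would share 0.00499. The simulated counts leave out real effects and the independent ones the shared controls, so part of the overlap in calls may come from these controls, which are too few to split.

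Of the CD8 T cell genes, Cd8a was listed at 0 in 8 of 9 libraries and had 0.362 bases per Mb in Hopx low replicate 3, while Cd8b1 had 14.8 to 31.1. Cd4 had 101 to 501 and the T cell receptor subunit gene Cd3e 147 to 339. Lists of neutrophil, gamma-delta T cell, CD8 T cell and mitochondrial genes had fewer than 3 tested members. Dendritic cell markers passed in no comparison.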

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

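Median scaling, the values as deposited with naive 1 and 2 as 1 sample, quantile normalization for lists, the block with naive replicates 1 and 2 as 1 sample, the removal of sex-linked rows and all settings of the 6-library fit as a result of its own were chosen after seeing the data. The design as written was fixed before the data were examined and was made an alternative afterwards. For single genes and lists a reversal was counted only where a value passed the threshold in either setting. The cause was not tested unless said. Same-numbered naive and Hopx low libraries deviated together with r of 0.59, 0.03 and 0.64, and naive and Hopx high libraries with 0.27, -0.18 and 0.09. With naive 1 and 2 averaged, that sample had r = 0.70 with Hopx low 1 and 0.31 with Hopx high 1. Naive 3 had r = 0.64 with Hopx low 3 and 0.09 with Hopx high 3. The deviations of the averaged sample and of naive 3 mirror each other, so these values are not independent and cannot settle whether naive numbers pair. In the fit to all groups a replicate block left the counts of 0 and 0 between Hopx high and Hopx low and kept the 15 list calls. Ribosomal protein genes (5 of 39 positive) passed downward only with the block. Their adjusted p with camera's preset correlation was 0.0626 without the block and 0.0231 with it. With an estimated correlation and no block it was 0.879.

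Between Hopx high and Hopx low the counts of 0 and 0 became 2 higher with a pseudocount of 5, 53 and 16 with these groups alone and 60 and 15 with a replicate block added; leaving out 1 replicate gave 0 to 45 higher and 0 to 12 lower. The design as written, with the values as deposited and 9 separate samples, gave 0 and 0. In the 6 Hopx libraries 53 and 16 became 0 and 0 with no filter, 23 and 5 with no trend, 32 and 9 with a pseudocount of 0.1 and 1 and 0 with the values as deposited; leaving out 1 replicate gave 3 to 61 and 2 to 22. Of the 69 genes and the 75 called with the replicate block, 57 were shared.

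For Hopx high against naive, 357 and 54 became 215 and 25 with no filter, 717 and 149 with naive 1 and 2 separate, 825 and 156 with that and a replicate block, 36 and 5 with these groups alone and a replicate block, and 568 and 177 with median scaling. The lower count became 273 with quantile normalization, 35 with a pseudocount of 0.1, 25 with a replicate block and 30 with these groups alone. Leaving out 1 replicate gave 137 to 2465 and 13 to 241.

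For Hopx low against naive, 32 higher became 7 with no filter, 57 with a pseudocount of 0.1, 222 with a replicate block and naive 1 and 2 separate, 11 with a replicate block, 164 with naive 1 and 2 separate, 4 with these groups alone, 126 with these groups and a replicate block, 54 with median scaling, 82 with the values as deposited and 101 in the design as written. The 1 lower gene became 3 with quantile normalization, 2 with no trend, with a pseudocount of 5 or with naive 1 and 2 separate, 5 with that and a replicate block, 8 with these groups and a replicate block, and 0 with the values as deposited or without sex-linked rows. Leaving out 1 replicate gave 15 to 2690 and 1 to 83; the highest counts came without naive replicate 3, which leaves naive with 1 sample, assumed to vary like the other groups.

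The list of IL-2 and STAT5 targets, Hopx low against naive, changed direction without naive replicate 3 (adjusted p = 0.616); leaving out 1 replicate gave 0.00322 to 0.616. With an estimated correlation 0 of the 15, 16 and 15 lists called between Hopx high and Hopx low, Hopx high and naive and Hopx low and naive passed, with fry 0, 6 and 0, with median scaling 15, 13 and 12 and with quantile normalization 15, 16 and 11. DESeq2 and voom were not run, since the values are base coverage and not read counts. Depth limits the comparisons with naive, where 1 read of 100 bases is worth up to 1.58 bases per Mb.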

Other observations

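The tests of library depth, of the share of coverage taken by a few rows, of cycling cells, of the sex-linked rows and of other splits of the libraries were written down only after the results they bear on were seen. The share of called genes on X and Y and the comparison with naive replicate 3 held out were set down before their values were seen.

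Hopx low libraries lay between naive and Hopx high for most genes called between the outer groups. Of the 357 genes higher in Hopx high than in naive, 341 (95.5%) had a Hopx low mean between both other means, as did 54 of the 54 lower genes. Among all tested genes the share was 44.0%. The Hopx low mean stood at a median of 64.4% of the way from naive to Hopx high for the higher genes and 41.8% for the lower ones. Genes picked for a large difference between the outer groups favour a middle position for the group left out, so these shares are descriptions and not tests. Ifng, the gene of the cytokine interferon gamma, was listed at 0 in the 3 naive and the 3 Hopx low libraries and at 2.08, 1.12 and 1.75 bases per Mb in the Hopx high libraries. Its mean lay below the filter, and it was not tested.

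The histone list was higher in Hopx high than in Hopx low, with a median log2 difference of 1.70 and 30 of 31 members positive (adjusted p = 0.0843 with an estimated correlation, 0.224 in the 6 Hopx libraries, and 0.145 with fry). After each of the 6 Hopx libraries was divided by its median gene, the median was 1.95, which argues against the share of coverage taken by a few rows as the whole cause. That value follows from the list median and the median of all genes, -0.25, both seen before, and is not separate evidence. Library depth was tested 3 times in turn: Hopx high replicate 3 against the highest Hopx low library (list medians 8.76 and 6.77), which rests on 1 library and excludes nothing, and members with a mean of at least 20 per Mb, which removed none of the 31 and tested nothing. The last test thinned the 6 libraries to 203 megabases, the depth of the shallowest, taking 100 bases as 1 read. It gave a median of 1.62 with 30 of 31 members positive. The list medians were log2 5.89 or more in every Hopx library, a level that thinning hardly changes. Its outcome was thus nearly fixed beforehand, and it decides nothing about depth. A larger share of cycling cells in the Hopx high samples may account for the pattern, as a hypothesis: 100% of the tested G2/M genes, a list with no histone member, lay above the median of all genes (list adjusted p = 0.115 with an estimated correlation, 0.224 in the 6 Hopx libraries), values of that list had been seen before, and no further test was made.

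Xist, which is transcribed from the inactive X chromosome, and 4 Y-linked genes parted the 3 naive from the 6 Hopx libraries in 5 of 5 rows, which is consistent with animals of different sex in the naive and the Hopx groups. Of the other genes called between Hopx high and naive, 0.743% lay on X or Y, against 3.15% of the tested genes, so genes on the sex chromosomes do not make up that set. An effect of sex on autosomal genes stays open and was not tested, since sex and group went together in these libraries.

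The low depth of naive replicates 1 and 2 could also add to the genes called against naive. Of the genes called higher without naive replicate 3, 35.4% were lower in naive replicate 3 than in every Hopx high library, against 19.8% of all tested genes. The share lay above that of all genes and below 2 times it, the bound set beforehand, so depth and group cannot be told apart for these genes. The Hopx high libraries that set the bar also served to call the genes, which by itself raises the share above that of all genes.

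The 69 genes called between Hopx high and Hopx low in the 6 Hopx libraries were set against the other splits of those libraries. The real split gave 69, the highest other split gave 2, and 1 of the 10 splits reached the real count. In the fit to all groups the real split gave 0 and the highest other split 0; every split reaches a count of 0, so the 10 of 10 splits with as many say nothing about it. With 10 splits no share under 0.05 can be had. The replicate numbers paired the Hopx libraries, and of the 4 splits that part all 3 pairs the real one gave 69 and the others 0.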
